A study of Mus musculus with 8 samples.

How the data were processed

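Total RNA of brain cortex was turned into 3' mRNA libraries with the QuantSeq forward kit, which primes on poly(A) tails and reads near the 3' end of each transcript, per the labels' protocols. The series holds 8 libraries, 4 from miR-33 KO and 4 from miR-33 WT mice that carry the APP/PS1 transgenes. Each library has 1 deposited file of raw read counts per Ensembl gene, whole numbers that the authors did not normalize. Reads were aligned with STAR 2.7.3a to GRCm39 and counted with HTSeq 0.9.1, per the submitters' processing notes. The annotation release, the strand setting of the counting and read filters are not given in the sources used here, so reads of antisense or overlapping genes cannot be told apart.

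Each file lists 53700 genes and, after them, the counter's own totals of unassigned reads, which were kept out of library sizes and tests. Of reads aligned to 1 place, 57.7% to 60.1% were assigned to a gene, 39.4% to 41.9% lay in no annotated gene and 0.405% to 0.443% were ambiguous. A further 13462750 to 29079132 alignments per library were listed as not unique, and counts of genes with near-identical copies leave those out. The mitochondrially encoded share of gene reads was 12.5% to 14.7%. Gene symbols were taken by Ensembl ID from a table that named 52093 of the IDs and left 1607 unnamed. Chromosome, distance between genes and 3' UTR sequences came from GENCODE M21 on GRCm38, joined by gene ID alone. No coordinates are printed, because that assembly is not the one the counts were made on.

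Genes were filtered with filterByExpr of edgeR 4.0.16 (R 4.3.3) at its defaults (10 counts, 15 in total), which left 13602 genes with 99.5% of gene reads. Counts were scaled by TMM, and KO was compared with WT by edgeR's quasi-likelihood test without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the log2 fold change over the square root of the test's F. The common biological coefficient of variation was 28.4%. The median log2 fold change was -0.0011 with TMM, and no scaling tried moved it by over 0.1. Values per library are CPM or log2 CPM with a prior count of 2. Intervals of a ratio of counts pool the reads of each group, so that they leave out the spread between libraries. Since reads carry no molecular identifiers, copies of 1 molecule may also count as separate reads. The depth behind the values runs from 3366968 to 8948743 gene reads, so that 3 reads correspond to 0.891 to 0.335 CPM.

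Gene lists of 30 kinds were fixed in advance, as were the main design, the rule for named genes and most alternatives. The lists cover miR-33 targets, sterol synthesis, LXR targets, fatty acid oxidation, disease-associated and homeostatic microglia, reactive astrocytes, astrocyte markers, complement, interferon response, lysosome, autophagy, amyloid processing and clearance, activity-induced genes, excitatory and inhibitory neurons, synaptic proteins, myelinating oligodendrocytes, oligodendrocyte precursors, endothelium, mural cells and fibroblasts, choroid plexus and ependyma, striatum, hippocampus, thalamus, blood cells, heat shock and ER stress, mitochondrially encoded genes, the nuclear respiratory chain and ribosomal proteins. Some lists share members. They were tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01, and again with the correlation estimated from the libraries, which called 0 of the 30 lists. The fry test, which asks whether a list's genes move one way on balance without comparing them with other genes, also called 0 lists. In its test for change in either direction 1 list passed, LXR targets (adjusted p = 0.0391). The mean log2 CPM of each list per library was compared by a 2-sided exact permutation test over 70 assignments, whose smallest p is 0.0286, so that no list can pass after adjustment over 30 lists unless most do.

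The miR-33-5p seed match was searched in the longest annotated 3' UTR of each tested gene. The shift of log2 fold changes was set beside that of 299 words with the base composition of CAATGCA and no CG. Genes near Mir33 were compared with the rest by a 2-sided Fisher's exact test.

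Named genes are 11 set in advance (Srebf2, Mir33, App, Psen1, Prnp, Abca1, Apoe, Trem2, Clec7a, Cst7 and Gfap), all called genes, those with the smallest p up to 20, and up to 4 members of each list with the smallest p. Of the last group only part is named here, chosen after the values were seen, and Hexa, Rpl15 and Ang were added outside the rule.

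No 2 libraries were duplicates, since the chi-square per degree of freedom between pairs was 6.86 to 16.1. Pearson's r of log2 CPM between libraries was 0.902 to 0.935 across genes, which are not independent replicates. The labels name no sequencing batch.

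The test was tried on simulated counts drawn with the means, library sizes and dispersion trend of these libraries. Simulated genes did not vary around that trend. Changes were planted in 67 genes at 1.5-fold, 67 at 2-fold and 66 at 4-fold. For KO against WT over 13602 genes the test recovered 11.9% of genes changed 1.5-fold, 43.3% of those changed 2-fold and 74.2% of those changed 4-fold, with 1 false call among 87. Recovery may be lower for real genes, whose dispersion varies, and where fewer genes change. A simulated list shift of -0.45 was called under both correlations, in data whose genes were independent, and a simulated seed shift of 0.05 was recovered as 0.0401 (exact p = 0.0286). With no simulated effect 0 genes and 0 lists were called. Genes were independent in all these simulations. They therefore do not measure false calls of lists whose genes move together, nor the recovery of a seed shift when genes vary together between libraries.

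Alternatives covered the scaling (RLE, upper quartile, library size only), the test (DESeq2 1.42.0, limma-voom with and without sample weights), the filter on low counts, mitochondrial genes, the replicate number as a block, and each library left out in turn. DESeq2 gave no adjusted p for 3 genes. Chosen after seeing the data were the thinning to equal depth, the analysis without WT 3 and KO 2, and the lists without Ttr and haemoglobin genes. Plots were drawn with matplotlib 3.10.9.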

Results

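Messenger RNA from the brain cortex of female mice aged 8 months was measured by 3' end sequencing. All mice carried the APP/PS1 transgenes, mutant APP and PSEN1 genes that drive amyloid plaque formation, on a mixed B6/C3H background. The 4 libraries of the KO group came from mice without microRNA-33 (miR-33), and the 4 libraries of the WT group from mice that kept it. Reads assigned to genes numbered 3366968 (WT 4) to 8948743 (WT 3) per library, and 17398 to 18132 genes had at least 1 read. The labels number the libraries within each genotype without stating that each is a separate animal, so p-values measure only the spread between these samples. Neither depth, detected genes, nor the mitochondrial share of gene reads differed between genotypes beyond the spread of libraries (2-sided exact permutation p = 0.657, 0.657 and 0.114).

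The deleted gene could not be checked in these counts. Mir33 had 0 reads in all 8 libraries, which allows up to 0.335 (WT 3) to 0.891 (WT 4) CPM (depth-scaled counts) at 3 reads, and a poly(A)-primed 3' library does not read a processed microRNA, so the value checks nothing. Srebf2, the sterol regulator whose intron holds Mir33, was at 62.6 ± 5.44 CPM in KO and 63.0 ± 8.48 CPM in WT (mean ± SD, n = 4 each), a log2 fold change of -0.01 (SE 0.15) that turned positive with library size as the only scaling. App, the mouse counterpart of one transgene, had a log2 fold change of 0.09 (SE 0.09). Prnp, which lends the transgenes their promoter and 3' end, had -0.02 (SE 0.09), which turned positive with library size as the only scaling. In a 3' library transgene reads could therefore be counted at Prnp rather than at App or Psen1, which was not tested. Psen1, which encodes the catalytic part of gamma-secretase, had -0.70 (SE 0.25). None of these genes passed the threshold (edgeR adjusted p = 0.997, 0.983, 0.997 and 0.909, in that order).

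The first comparison asks which transcripts differ in the amyloid-bearing cortex when miR-33 is missing. In KO, 3 transcripts fell and 1 rose among 13602 genes tested. Mpeg1, which encodes the pore-forming perforin-2 of macrophages and microglia, fell from 46.8 ± 8.36 CPM in WT to 18.3 ± 5.46 CPM in KO (mean ± SD, n = 4 each), a log2 fold change of -1.35 (SE 0.22, edgeR adjusted p = 0.0296). Rnase4, a secreted ribonuclease, fell from 46.0 ± 10.3 to 15.0 ± 6.87 CPM, a log2 fold change of -1.60 (SE 0.27, edgeR adjusted p = 0.0296). Nr4a2, an orphan nuclear receptor induced by neuronal activity, rose from 82.1 ± 13.2 to 196 ± 70.4 CPM, a log2 fold change of 1.25 (SE 0.21, edgeR adjusted p = 0.0296). Gm8420, annotated as a processed pseudogene, had 1 read over the 4 KO libraries against 254 over the 4 WT libraries (edgeR adjusted p = 5.64e-04). Its depth-scaled ratio of WT to KO was 213, with a counting interval of 37.9 to 8458 (95%, exact binomial over pooled reads, without the spread between libraries). Gm8420 is a near-identical copy of the ribosomal protein gene Rpl15, so which of both loci its reads came from is uncertain. Rnase4 shares its locus with Ang. Reads that overlap both genes would be among the ambiguous reads left out, and how far this touches Rnase4 was not tested. In each of the 4 genes no KO library overlapped a WT library. Across all genes tested this held for 457 genes (3.36%), against 2.86% by chance, and 687 genes had an unadjusted p under 0.05, against 680.1 by chance.

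Gm8420 passed the threshold without any single library but missed it with limma-voom (adjusted p = 0.204), with limma-voom with sample weights (0.0967) and without WT 3 and KO 2 together (0.0650), whereas Mpeg1 missed it without KO 1, KO 2, KO 3, WT 2, WT 3 or WT 4 (adjusted p = 0.0921 to 0.292), Rnase4 without KO 1, KO 2, KO 4, WT 1, WT 2 or WT 4 (0.0793 to 0.292), and Nr4a2 without any library but KO 3 (0.0780 to 0.333). With limma-voom 0 genes passed (889 at an unadjusted p under 0.05), with DESeq2 6 passed but Nr4a2 missed (adjusted p = 0.0794), with depth thinned to the smallest library Rnase4 missed (0.157), with no filter on low counts 40 of 23712 genes passed, and without WT 3 and KO 2 together 0 passed (632 at an unadjusted p under 0.05).

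**Figure D1:**
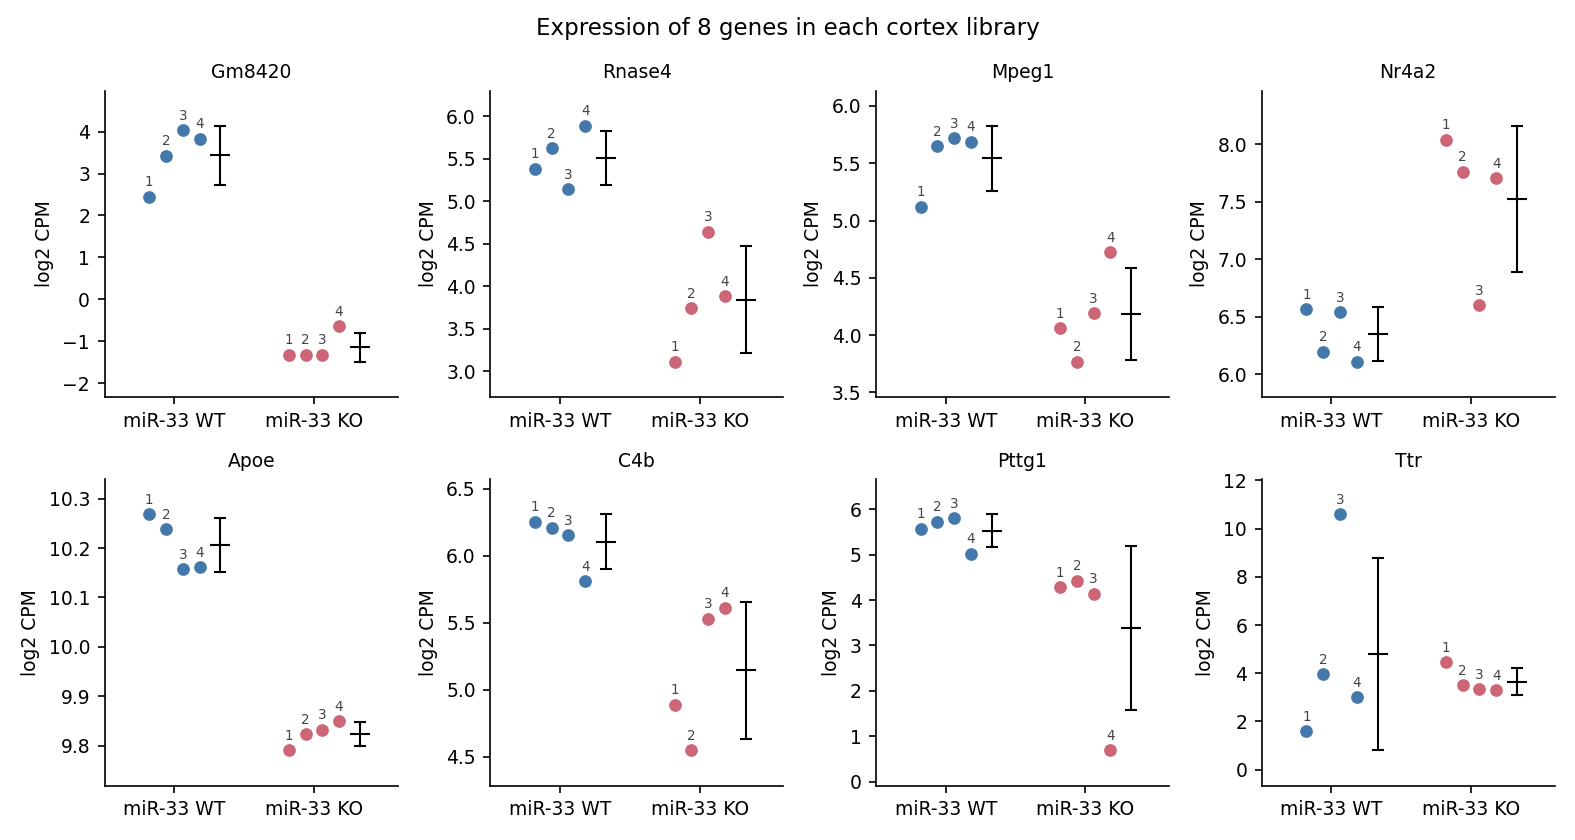
Each panel plots log2 CPM (vertical axis, a log scale, with a prior count of 2) of 1 gene in the WT (blue) and KO (red) libraries, each point 1 library with its replicate number, with the mean and SD as bars. The KO libraries lie below the WT libraries in Gm8420, Rnase4, Mpeg1, Apoe, C4b and Pttg1, of which the first 3 passed the threshold, the KO libraries lie above in Nr4a2, and WT 3 stands apart in Ttr.

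Genes with the next smallest p did not pass the threshold, and their values are given without a call. Apoe, the main lipid carrier of the brain, was at 906 ± 15.3 CPM in KO and 1182 ± 45.5 CPM in WT (mean ± SD, n = 4 each), a log2 fold change of -0.38 (SE 0.08, edgeR adjusted p = 0.397). Its groups did not overlap, and it passed with DESeq2 (adjusted p = 0.00462) and with limma-voom with sample weights (adjusted p = 0.0471), its adjusted p being 0.00462 to 0.994 over the alternatives. Irf8, a transcription factor of microglia, had a log2 fold change of -0.97 (SE 0.22), and the complement genes C4b and C1qa had -0.92 (SE 0.21) and -0.83 (SE 0.21). Pttg1, which encodes securin, had -1.67 (SE 0.40), and Vgll3, a transcription cofactor, had -2.62 (SE 0.63) and passed with DESeq2 (adjusted p = 0.0226, range 0.0226 to 0.994 over the alternatives). Dnajb5, a heat shock protein cofactor, had 0.94 (SE 0.18, edgeR adjusted p = 0.128) and passed with DESeq2 (adjusted p = 0.00462) and without KO 3 (adjusted p = 0.0277), with a range of 4.24e-04 to 0.958 over the alternatives. Nptx2, a secreted synaptic pentraxin, had 1.02 (SE 0.25), and Aars, which charges alanine tRNA, had 0.78 (SE 0.17). Cdyl2 (1.05), Senp5 (0.64), Rb1 (0.78), Erp44 (0.95), and the unnamed loci Gm37407 (0.94) and AC123927.2 (2.62) completed the 20 genes of smallest p together with Ttr, which was at 1.59 to 4.47 log2 CPM in 7 libraries and at 10.59 in WT 3.

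The second comparison asks which gene groups moved together, over 30 lists fixed before the data were examined. Both microglial lists were lower in KO, relative to the other genes. Of the 29 tested genes that mark disease-associated microglia, the state that surrounds plaques, 25 had a negative log2 fold change (mean -0.45, camera adjusted p = 7.66e-09 with a preset correlation, adjusted p = 0.289 with an estimated correlation). Members with the smallest p were Clec7a, a pattern recognition receptor (-1.03, SE 0.33), Lgals3, galectin-3 (-1.46, SE 0.54), the antigen presentation subunit B2m (-0.54, SE 0.19) and the protease inhibitor Cst7 (-0.63, SE 0.23). Trem2, the lipid-sensing receptor of microglia, had -0.60 (SE 0.26). Single libraries moved B2m to -0.28 (without WT 2) and Trem2 to -0.996 (without KO 3, which at 44.0 CPM lay above all WT libraries). None of the 29 passed over all genes tested, and 0 passed adjusted over the list alone. The mean log2 CPM of the list was 4.53 ± 0.26 in KO and 4.97 ± 0.07 in WT (mean ± SD, n = 4 each), a difference of -0.44 (95% interval -0.77 to -0.12, exact permutation p = 0.0286), the smallest p that 70 assignments allow, which did not pass adjustment over the 30 lists (adjusted p = 0.750). With SDs this unequal the interval is too narrow. Of the 19 tested markers of homeostatic microglia, 18 had a negative value (mean -0.35, camera adjusted p = 4.03e-06, adjusted p = 0.289 with an estimated correlation), and the difference in mean log2 CPM was -0.34 (exact permutation p = 0.0857). Examples were the fractalkine receptor Cx3cr1 (-0.47, SE 0.15) and the growth factor receptor Csf1r (-0.45, SE 0.19), and the lysosomal enzyme subunit Hexb fell by 0.53 (SE 0.14) as the 1 gene that passed adjusted over the list alone, against 0 over all genes tested.

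Lists of lysosome, complement, astrocyte reactivity and interferon genes were also lower in KO under the preset correlation. The lysosome list (32 tested genes, mean -0.18) had a camera adjusted p = 5.41e-05, and adjusted p = 0.552 with an estimated correlation. Adjusted over the list alone 5 of its genes fell, against 0 over all genes tested. They were Hexb, the microglial membrane protein Laptm5 (-0.69, SE 0.18), the proteases Ctss (-0.60, SE 0.19) and Ctsd (-0.48, SE 0.15), and Hexa (-0.49, SE 0.16), which lies outside the naming rule and was added after its value was seen. The lysosome list shares 5 tested members with the disease-associated list and 1 with the homeostatic list. The complement list (10 tested genes, mean -0.28) had a camera adjusted p = 0.00848, and adjusted p = 0.552 with an estimated correlation. Of its genes 6 had a negative and 4 a positive log2 fold change. Adjusted over the list alone C4b and C1qa fell, 2 genes against 0 over all genes tested. The reactive astrocyte list (20 tested genes, mean -0.33) had a camera adjusted p = 0.0117, and adjusted p = 0.635 with an estimated correlation. Its members with the smallest p were Aspg (-1.18, SE 0.47), the interferon-induced GTPase Iigp1 (-1.34, SE 0.54), the astrocyte filament gene Gfap (-0.49, SE 0.23) and the protease inhibitor Serpina3n (-0.86, SE 0.41), with 0 genes past the threshold adjusted over the list alone and 0 over all genes tested. Single libraries moved Iigp1 to -0.53 (without WT 2), Gfap to -0.27 (without KO 1) and -0.89 (without KO 4, which at 251 CPM lay above all WT libraries), and Serpina3n to -0.53 (without KO 1) and -1.60 (without KO 4). The interferon list (19 tested genes, mean -0.27) had a camera adjusted p = 0.0382, and adjusted p = 0.887 with an estimated correlation, with 0 genes past the threshold either adjusted over the list alone or over all genes tested. Its leading members were Lgals3bp (-0.76, SE 0.29) and the transcription factor Irf9 (-0.67, SE 0.28, -0.43 without WT 2), and its mean log2 CPM varied within groups, from 2.25 (KO 1) to 3.65 (KO 4) in KO and from 2.55 (WT 3) to 4.06 (WT 2) in WT.

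In mean log2 CPM per library none of the latter 4 lists differed beyond the spread (exact permutation p = 0.114 for lysosome, 0.314 for complement, 0.143 for reactive astrocytes and 0.629 for interferon). The 2 microglial lists and the lysosome list kept their camera call without any single library. The complement call was lost without KO 1 (adjusted p = 0.127), without WT 2 (0.173) and with limma-voom (0.0545), the reactive astrocyte call without KO 1, KO 2, KO 3 or WT 2 (0.0640 to 0.317), and the interferon call without KO 1, KO 2, KO 3 or WT 4 (0.0592 to 0.507), with limma-voom (0.204), and without WT 2, where its direction turned (0.959).

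Genes induced by neuronal activity were higher in KO, as a list. Of 24 tested genes 21 had a positive log2 fold change (mean 0.46, camera adjusted p = 4.46e-08, adjusted p = 0.552 with an estimated correlation). Nr4a2 and Nptx2 rose adjusted over the list alone, 2 genes against 1 over all genes tested. Ptgs2, which encodes cyclooxygenase-2, had 1.08 (SE 0.41, 0.66 without KO 1), and the phosphatase Dusp6 had 0.48 (SE 0.21, 0.32 without WT 4). The mean log2 CPM of the list was 5.25 ± 0.46 in KO and 4.82 ± 0.36 in WT (mean ± SD, n = 4 each, exact permutation p = 0.257), with KO 1 at 5.93 and the other KO libraries at 4.95 to 5.16. Without KO 1 the difference of 0.43 became 0.20, and without WT 4 it became 0.28.

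**Figure D2:**
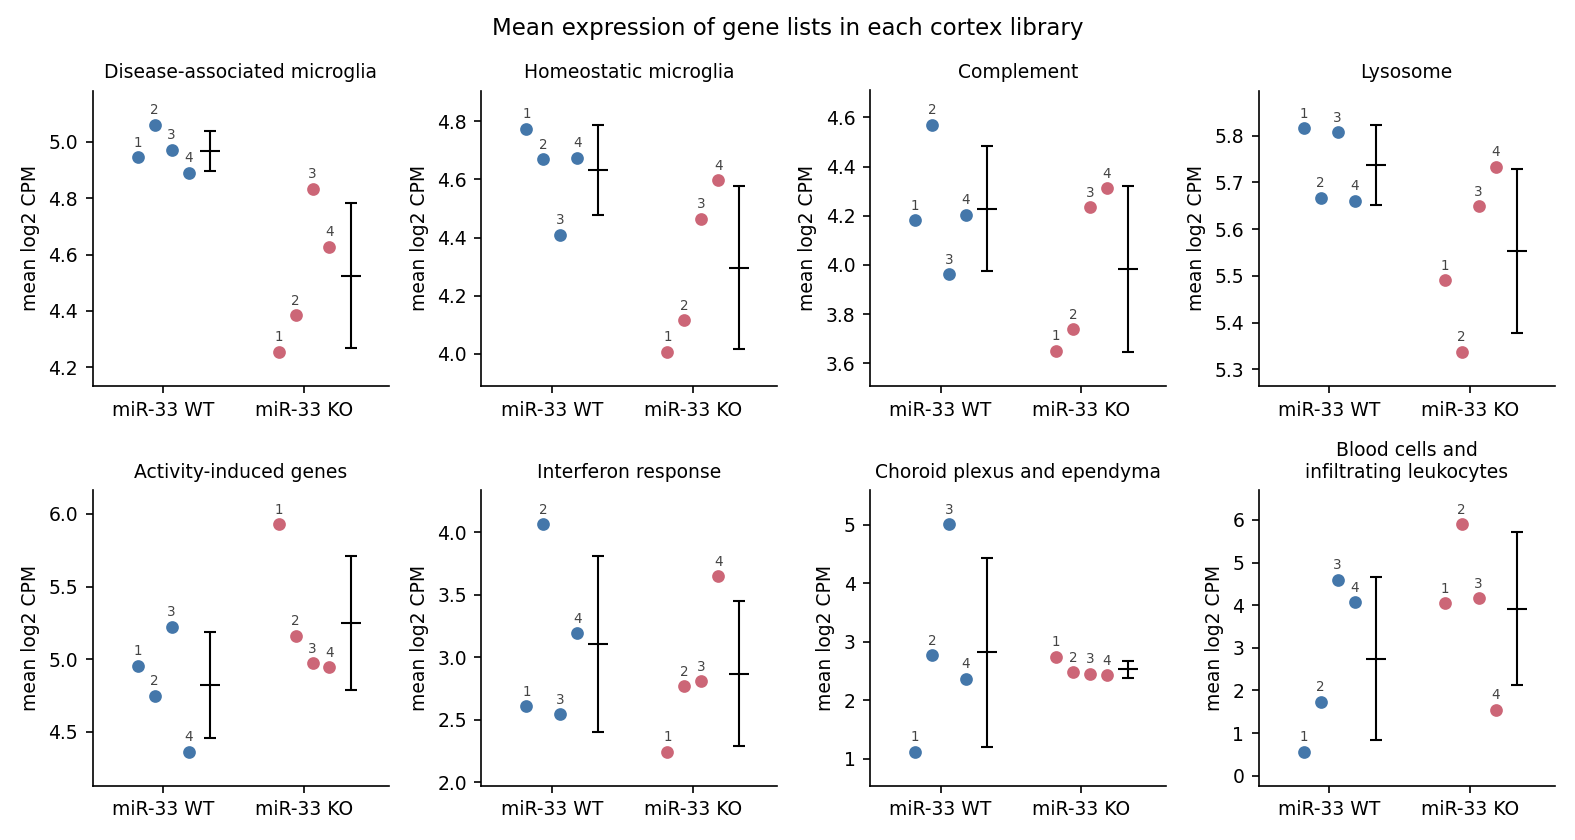
Each panel plots the mean log2 CPM over the tested genes of 1 list (vertical axis, a log scale) in the WT (blue) and KO (red) libraries, each point 1 library with its replicate number, with the mean and SD as bars. The disease-associated list is lower in all 4 KO libraries (4.25 to 4.83) than in any WT library (4.89 to 5.06), and WT 3 has the highest choroid plexus value (5.01).

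The third comparison asks whether mRNAs that miR-33 could repress were higher in its absence. No shift beyond the spread of libraries was shown for them as a set. Of 12001 tested genes with an annotated 3' UTR, 2078 held a match to the miR-33-5p seed and 9923 held none. A match was CAATGCA, which pairs with bases 2 to 8, or AATGCAA, the 7mer-A1 form with a shorter pairing and an A. The mean log2 fold change of genes with a match was 0.0081 above that of genes without, and the difference per library was 0.0051 between KO and WT (95% interval -0.0269 to 0.0371, 2-sided exact permutation p = 0.714). Among 299 control words with the base composition of CAATGCA and no CG, 12 gave a shift as high. The match thus ranked above 96.0% of the words, whose median shift was -0.0063. That rank looks in the upward direction only and does not weigh the spread between libraries. The shift was near 0 with 8mer sites alone, -0.000215, and its sign turned. Genes with a match had longer 3' UTRs (median 2756 against 1096 bases), and against 2013 control genes matched on UTR length, GC and expression the shift was 0.0122 and the difference per library 0.0116 (exact permutation p = 0.0857). The list of reported miR-33 targets (24 tested genes, 17 with a match) was not called (camera adjusted p = 0.529). Its member Abca1, the cholesterol exporter, was at 22.9 ± 5.46 CPM in KO and 26.5 ± 7.87 CPM in WT (mean ± SD, n = 4 each), a log2 fold change of -0.22 (SE 0.25, edgeR adjusted p = 0.983), which without WT 2 was 0.0015. Cpt1a, of mitochondrial fatty acid import, had 0.41 (SE 0.31), Prkaa1, a subunit of the energy sensor AMPK, had -0.70 (SE 0.41, -0.46 without KO 2), and the cell cycle gene Ccnd1 had -0.33 (SE 0.15, -0.15 without WT 4).

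Lists of lipid handling were not called by camera. The LXR target list was the 1 list that passed the fry test for change in either direction (adjusted p = 0.0391). The camera adjusted p was 0.526 for sterol synthesis, whose members with the smallest p were Tm7sf2 (1.24, SE 0.44) and Sqle (0.40, SE 0.18), and 0.818 for fatty acid oxidation. It was 0.818 for targets of the sterol receptor LXR, where Apoe fell adjusted over the list alone, 1 gene against 0 over all genes tested, and Mylip had -0.81 (SE 0.30). For these lists of sterol synthesis, fatty acid oxidation and miR-33 targets, 0 genes passed adjusted over the list alone and 0 over all genes tested. No called gene lay within 10 Mb of Mir33 on chromosome 15 (0 of 244 genes tested there, 4 of the rest, Fisher's exact p = 1). With so few called genes, 0 in such a window is what chance would mostly give, so this count decides little. An unadjusted p under 0.05 was reached by 6.15% of these 244 genes and by 5.03% elsewhere (Fisher's exact p = 0.378).

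Other lists were not called either. Amyloid processing and clearance had a camera adjusted p = 0.545, with Apoe and Ttr lower adjusted over the list alone, 2 genes against 0 over all genes tested, Ttr through WT 3 alone, without which its log2 fold change was 0.63. Among neuronal lists the camera adjusted p was 0.843 for excitatory neurons (Neurod6 0.47, SE 0.17), 0.843 for inhibitory neurons (Kcnc2 0.47, SE 0.18) and 0.818 for synaptic proteins. Among glial and vascular lists it was 0.843 for astrocyte markers, 0.843 for myelinating oligodendrocytes, 0.192 for oligodendrocyte precursors, 0.843 for endothelium, and 0.818 for mural cells and fibroblasts. It was 0.818 for autophagy, whose mean log2 fold change was -0.02 while its median was 0.08 and its camera direction upward. In each of these 9 lists 0 genes passed adjusted over the list alone and 0 over all genes tested. The nuclear respiratory chain list had an adjusted p of 0.127 and ribosomal proteins of 0.0777, again with 0 genes in either count. The mitochondrially encoded list had an adjusted p of 0.192, with mt-Rnr1 lower by list-only adjustment (-0.21, SE 0.06), 1 gene adjusted over the list alone against 0 over all genes tested.

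Markers of neighbouring tissue and of blood varied between libraries more than between genotypes. The choroid plexus and ependyma list (4 tested genes) averaged 5.01 log2 CPM in WT 3 and 1.13 to 2.77 in the other 7 libraries, with a camera adjusted p = 0.702, and Ttr was its 1 gene past the threshold adjusted over the list alone, against 0 over all genes tested. The blood list (5 tested genes) averaged 0.57 (WT 1) to 5.90 (KO 2) log2 CPM, with a camera adjusted p = 0.144. Adjusted over the list alone its haemoglobin genes Hba-a1 (2.37, SE 0.83) and Hbb-bt (2.12, SE 0.82) rose and the leukocyte gene Ptprc fell by 0.73 (SE 0.31), 3 genes against 0 over all genes tested. The haemoglobin values rest on KO 1, KO 2 and KO 3, since KO 4 (2.92 CPM of Hba-a1 and 0.486 CPM of Hbb-bt) lay below WT 3 and WT 4, and without KO 2 they were 1.38 and 1.16, while Hba-a1 was 4.51 without WT 3. Lists of striatum, hippocampus and thalamus had camera adjusted p = 0.469, 0.818 and 0.908, with 0 genes past the threshold adjusted over the list alone and 0 over all genes tested. The heat shock and ER stress list had a camera adjusted p = 0.818, and Chac1 and Atf4 rose adjusted over the list alone, 2 genes against 0 over all genes tested.

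**Figure D3:**
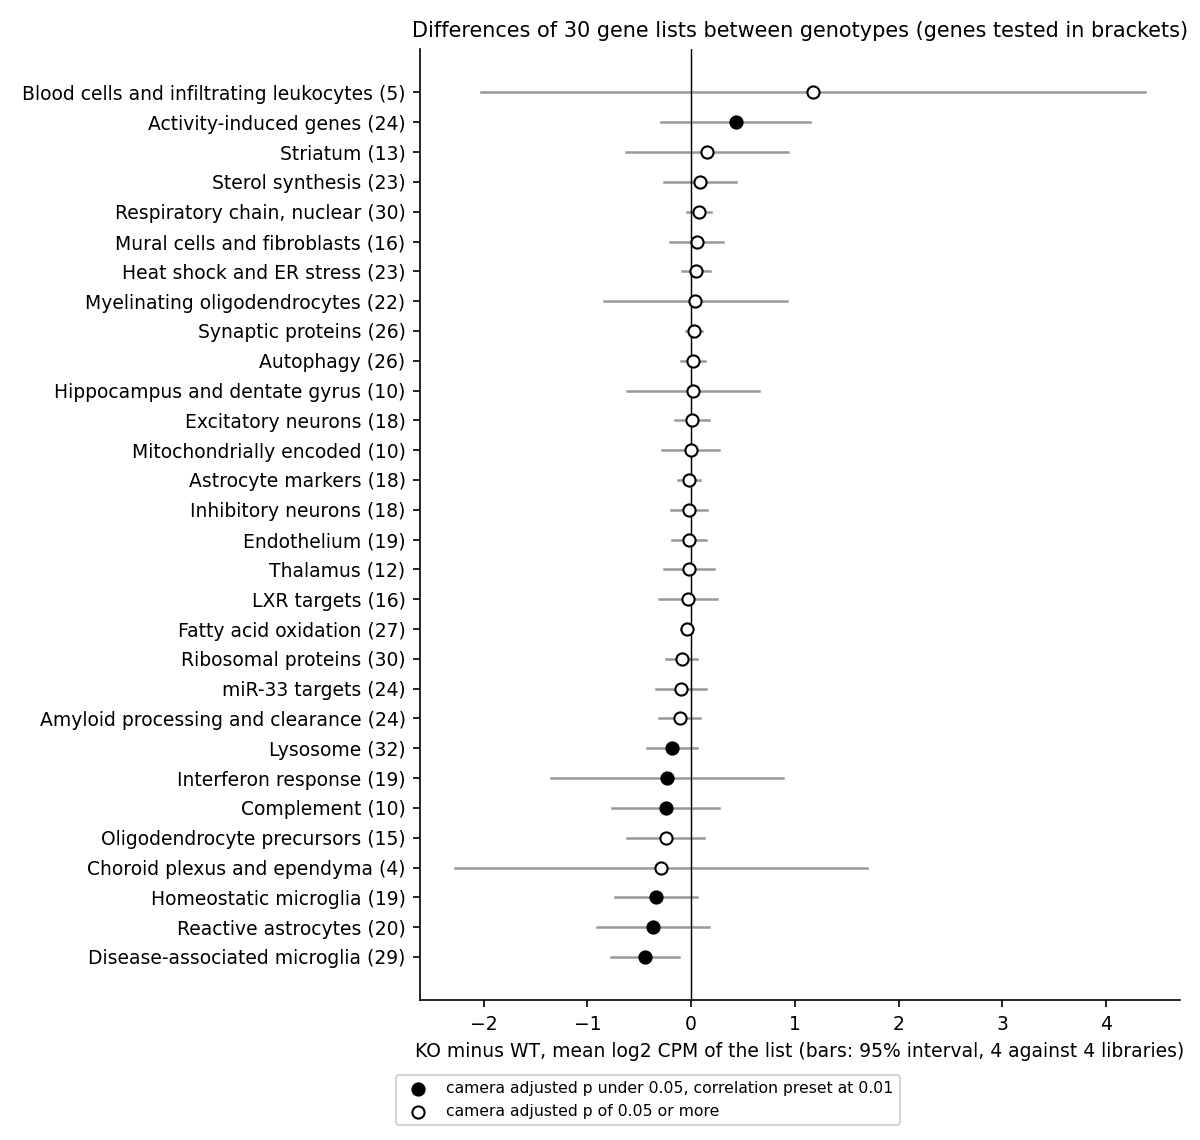
Differences in mean log2 CPM between KO and WT (horizontal axis, a log2 scale) for 30 gene lists, with bars for the 95% interval over 4 against 4 libraries and the number of tested genes in brackets, filled where camera with a preset correlation called the list. The interval of the disease-associated microglia list runs from -0.77 to -0.12, and the widest intervals are those of the blood and choroid plexus lists. Intervals are too narrow where the SDs of the groups differ.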

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

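Chosen after the results were seen were the tests on the chromosomes of Gm8420, Rnase4 and Pttg1 and on the neuronal lists, as was setting their limits and that of the stress list against the activity-induced difference with each library left out. Thinning was added once the depths were seen, but before its result. For WT 3 and for depth an exact p under 0.05 had also been asked for in advance and was missed, so that judging both by the interval or the share kept was decided after the result was seen.

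Chance cannot be excluded for either count of calls. Splitting the 8 libraries into 4 and 4 in all 35 ways, 3 splits, the real one included, called at least the 4 genes of the real one, and the highest other called 50. That split, singled out for its count, set KO 1, KO 4, WT 2 and WT 4 against the rest. So many calls may point to a structure of the samples, whose nature was not tested, nor whether chance gives such a highest count. The first principal component is the axis of largest variation between libraries (19.6%). On it KO 1, KO 4, WT 2 and WT 4 lay at -0.771 to 44.5 and the rest at -53.1 to -5.01. The real split called 7 lists, 9 of 35 splits, the real one included, called at least as many, and the highest other called 13.

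The first pattern weighed is the lower level of microglial and complement genes in KO. Tissue of another region in WT 3 is argued against, since without WT 3 the disease-associated list kept 0.989 of its difference (-0.44, 95% interval -0.79 to -0.08), although its exact permutation p of 0.0571 missed the threshold. A difference in depth is argued against as well, since over 20 draws thinned to 3366968 reads at least 0.875 of the difference remained, although the exact permutation p was under 0.05 in 15 draws and reached 0.0571 in the rest. Fewer microglia in all states and a milder reaction of the same cells cannot be told apart here, because the disease-associated list fell by 0.11 more than the homeostatic list, which is within the spread (exact permutation p = 0.457). The genotype itself stays open beside chance, and a smaller plaque load, which these data do not measure, may be another route.

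The second pattern is the near absence of Gm8420 and the low level of Rnase4 and Pttg1 in KO, of which Pttg1 did not pass the threshold. DNA carried along with the Mir33 allele is argued against, since 0 of the 3 genes lie on chromosome 15 with Mir33 (they lie on 1, 14 and 11 in GRCm38). A shift of Gm8420 reads to counts of its copy Rpl15 is argued against. The upper 95% limit of the KO minus WT difference of Rpl15 was 7.30 CPM, below the 11.2 CPM that Gm8420 lost. That limit was set over all libraries, and the log2 fold change of Rpl15 ran from -0.41 to -0.0951 with 1 library left out. Reads that fit both copies were left out as not unique. A move of reads into that class would not raise Rpl15, so it stays open. Background haplotypes that differ between the groups may be a source in a mixed B6/C3H stock, and 8% of the 150 tested genes within 5 Mb of the 3 genes had an unadjusted p under 0.05 against 4.99% elsewhere, but the odds ratio of 1.65 (Fisher's exact p = 0.128) had an upper limit of 3.00, so this and the genotype cannot be told apart.

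The third pattern is the higher level of activity-induced genes in KO. A larger share of neurons, as the whole cause, would raise all neuronal markers by about the 0.43 to be explained. The upper 95% limits were 0.175 for excitatory neurons, 0.149 for inhibitory neurons and 0.102 for synaptic proteins. These lie below the bound of 0.214 set from that difference, which argues against neurons as the whole cause of a difference of 0.43. The activity-induced difference itself had a 95% interval of -0.29 to 1.15, however, so for a smaller true difference the limits decide nothing. With each library left out in turn the limit stayed below the activity-induced difference of the same libraries in 8 of 8 cases for inhibitory neurons and for synaptic proteins, and in 7 for excitatory neurons, whose limit was 0.225 against 0.20 without KO 1 and whose difference from the activity-induced list had an exact permutation p = 0.171. Stress of handling stays open, since the upper 95% limit of the heat shock and ER stress list was 0.179, below the same bound set in advance, but 0.274 without KO 1, and 12 of its tested genes had a positive and 11 a negative log2 fold change, so that its mean decides little. Chance, the state of the sample behind KO 1 and the genotype stay open too, as the difference was 0.20 without KO 1.

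Other results stood apart because 1 library lay far from the other 3 of its group, which chance alone gives in about 1 in 20 groups, and 10 of 192 groups looked at did so. Gm8420 was at -0.64 log2 CPM in KO 4, which held its 1 read, against -1.32 in the other KO libraries. Mpeg1 was at 5.12 log2 CPM in WT 1 and at 5.65 to 5.72 in the other WT libraries. Pttg1 was at 0.69 log2 CPM in KO 4 (5 reads) and at 4.14 to 4.42 in the other KO libraries. Hspa8, a constitutive chaperone, was at 5.76 log2 CPM in KO 4 and at 7.22 to 7.28 in the other KO libraries. Ptprc was at 2.50 log2 CPM in KO 1 against 3.69 to 3.76, and Rpl15 at 4.26 in KO 1 against 4.85 to 4.94. Mean log2 CPM of a list stood apart for astrocyte markers in KO 4 (6.71 against 6.57 to 6.59), autophagy in KO 2 (5.30 against 5.24 to 5.25), oligodendrocyte precursors in WT 2 (4.51 against 4.07 to 4.11) and endothelium in KO 3 (4.11 against 3.99 to 4.01).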

How the results depend on the processing

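Thinning to equal depth and the analyses without WT 3 and KO 2 or without Ttr and haemoglobin genes were chosen after the data were seen, and the other alternatives before. The number of genes called stayed at 4 with RLE, upper quartile and library size scaling, a filter at 1 CPM and no mitochondrial genes, and was 6 with DESeq2 (3 shared), 3 with sample weights in limma-voom (2 shared, Gm8420 and Nr4a2 lost) and 3 after thinning. It was 0 with limma-voom (889 at an unadjusted p under 0.05, cause not tested), 0 without WT 3 and KO 2 (fewer samples), 40 without a filter on low counts, where the variance prior became infinite against 14.1 degrees of freedom, and 1 to 4 with 1 library left out. Lists called numbered 7 to 10 in other settings, 9 without WT 3 and KO 2 (7 shared) and 4 to 10 with 1 library left out. They numbered 0 with an estimated correlation and 0 with fry. With an estimated correlation camera allowed more for correlated genes in the lists called at the preset value. It also tested on the 6 residual degrees of freedom, and the effects of both were not told apart. For fry the cause was not tested. Lists with an exact permutation p under 0.05 numbered 1, but 0 as mean z scores, 0 in the single thinned draw used for all lists (in 15 of 20 other draws the disease-associated list stayed under 0.05), and 0 to 5 with 1 library left out. Without WT 3 and KO 2 such lists numbered 0. The remaining libraries allow too few assignments for any exact p under 0.05, so that 0 decides nothing.

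Directions turned for values near 0. Srebf2 had 0.0136 with library size only and 0.0289 without WT 3 and KO 2, Prnp had 0.00796 with library size only, and with 1 library left out Srebf2 ran from -0.0913 to 0.0402, Prnp from -0.0605 to 0.0187 and Abca1 from -0.32 to 0.0015. Ttr ran from -5.31 to 0.63 and was at 0.70 without WT 3 and KO 2, since its reads lie in WT 3. The seed shift was -0.000215 with 8mer sites, -0.0013 with 7mer-m8 or 8mer sites and -0.0031 to 0.0205 with 1 library left out, and the cause was not tested. The interferon list's adjusted p ran from 1.02e-05 to 0.959 with 1 library left out, and its direction turned without WT 2.

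Some lists that were not called passed in other settings. Without WT 4 these were myelinating oligodendrocytes (adjusted p = 5.58e-06, lower), striatum (0.00680, higher) and blood (0.0279, higher). Blood also passed without KO 4 (1.73e-04) or WT 3 (0.00464), choroid plexus without WT 1 (0.0146), and oligodendrocyte precursors without KO 4 (0.0498). The mitochondrial list passed without WT 3 (0.0490), with DESeq2 (0.0123), with limma-voom (0.00487), with sample weights (1.68e-04) and without WT 3 and KO 2 (0.0278). The respiratory chain list passed without KO 2 (0.0467), WT 1 (0.0217) or WT 3 (0.0272), with sample weights (0.0468) and without WT 3 and KO 2 (0.00948). Ribosomal proteins passed without KO 1 (0.0223), KO 4 (0.0120) or WT 1 (0.0231), with limma-voom (0.0210) and with sample weights (0.0177). Depth limits genes of few reads, and in simulated counts of this depth 43.3% of 2-fold changes were recovered, a share that may be lower for real genes.

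With the replicate number as a replicate block 5 genes and 7 lists were called, Pttg1 being added. No pairing by number was shown, since deviations of same-numbered libraries from their group means correlated at -0.0437 to 0.105, 1 of 4 pairs exceeded 0.1, and 2 of 8 libraries correlated best with their own number. That 1 pair, KO 4 with WT 4, had the highest correlation of all pairs of a KO and a WT library. A pairing is therefore not excluded.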

Other observations

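The genes given here were chosen after their values were seen, and no list of them was tested. Chac1, which degrades glutathione and is a target of ATF4, had a log2 fold change of 2.13 (SE 0.63), Atf4 itself 0.53 (SE 0.16) and Aars, a tRNA ligase that ATF4 induces, 0.78 (SE 0.17), none past the threshold over all genes tested (edgeR adjusted p = 0.904, 0.904 and 0.404). Atf4 lies on chromosome 15 at 1.94 Mb from Mir33 in GRCm38. Hspa8 had -0.56 (SE 0.24, -0.31 without KO 4 and -0.34 without WT 3), and the heat shock and ER stress list that holds Chac1, Atf4 and Hspa8 was not called.

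Also looked at after the results were seen, the disease-associated microglia list had its smallest camera adjusted p in the real split of the libraries (7.66e-09), and the next smallest of the other 34 splits was 2.02e-08, from setting KO 1, KO 2, KO 4 and WT 4 against the rest. In 14 of these 34 splits the list had an adjusted p under 0.05. Of these, 9 keep 3 KO libraries together and so hold part of any genotype difference, and the other 5 keep KO 1 and KO 2 together. The mean of this list was lowest in KO 1 (4.25) and KO 2 (4.38), and KO 3 (4.83) came close to WT 4 (4.89).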
